A study of Homo sapiens with 16 samples.

How the data were processed

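RNA was measured on Affymetrix arrays in 16 xenograft tumors grown from 4 derivatives of PC-3, an established human prostate cancer cell line. Per the labels' protocols, 1000000 cells were injected under the skin of nude mice, which lack mature T cells, tumors were collected once they measured 5 mm or more across, and 100 ng of total RNA per tumor was made into biotin-labelled cRNA. The lines named mock and mock/cre+ had short telomeres and no exogenous hTERT. Line LhTERTL had long telomeres and carried exogenous hTERT, the catalytic subunit of telomerase, and line LhTERTL/cre+ had long telomeres without exogenous hTERT. Each line gave 4 independent tumors, so n = 4 in each of the 4 groups. The p-values for genes in the main fit therefore rest on the spread between tumors of the same line, pooled over the 4 lines. Some tests of gene lists and those of genes along chromosomes set genes against other genes instead. Only 2 lines stood for each telomere state, and no p-value of the main fit measures the spread between lines. A tumor also holds mouse cells, whose transcripts can bind to some probes of a human array.

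The authors summarised the arrays with RMA (robust multi-array average, a background correction, quantile normalization and probe set summary), per the submitters' processing notes. Its version, and the array model, are not given in the sources used here. The deposited values were read as log2 expression values, the scale RMA returns, because the file header names no log base. They ranged from -5.72 to 5.04, and the median of every probe set over the 16 arrays was 0 within 5.0e-07, so the deposited values are log2 signals relative to that median. Differences between groups are kept by this centring, whereas the signal level of a probe set and its height above background are lost. A second deposited table held the same values, with 0 differences.

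The table held 54675 probe sets. Of these, 41477 named 1 gene and gave 20283 genes, 961 named several genes and were left out, 12172 named no gene, 3 had a symbol without a gene ID and 62 were control probe sets. The names came from the deposited annotation. Symbols were updated through the Entrez ID in the RefSeq gene table of GRCh38.p14, which held 19252 of the 20283 genes, and the file's own symbol was kept for the other 1031. This also restored the names of 59 probe sets whose symbol the file held as a date. The reference table served only for names and for the order of genes along chromosomes.

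The plan fixed before the data were examined was to take the probe set with the highest mean per gene, to model the spread with a trend over the mean, and to try filters on dim probe sets. Centred values carry no mean level, so none of these was usable. The mean of all probe sets of a gene, the other summary set out beforehand, was used for all genes, without a filter and without the trend. A total of 10740 genes had more than 1 probe set, and the text says so for TERT, CDH1 and CDH2, whose probe sets went apart.

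A means model of the 4 groups was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, with 12 residual and 5.22 prior degrees of freedom). The 6 comparisons were long against short telomeres averaged over both pairs of lines, LhTERTL against mock, LhTERTL/cre+ against mock/cre+, the difference between these 2 effects, mock/cre+ against mock, and LhTERTL/cre+ against LhTERTL. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment over the 20283 genes in each comparison, and a gene passed at an adjusted p under 0.05. The words rose, fell and changed are used for genes that passed. A ± beside a log2 fold change is its standard error from that fit, and a ± beside a group mean is the SD over 4 tumors. The number of arrays limits the precision.

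A set of 25 general gene lists was fixed before the data were examined and was not chosen on these samples. They cover interferon-stimulated genes, antigen presentation, epithelial junction and keratin genes, mesenchymal genes, prostate luminal, basal epithelial, neuroendocrine and stem cell genes, telomere maintenance, cell cycle, p53, NF-kB, TGF-beta and Wnt targets, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis and cancer-testis antigens. The other 7 hold markers of cells that a mouse tumor can contain, namely fibroblasts, endothelium, macrophages and leukocytes, red blood cells, skeletal muscle, adipocytes and skin keratinocytes. No list shared a gene with another. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 25 lists. Camera compares a list with all other genes, while fry's test asks whether the list's genes move on balance in 1 direction.

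Genes are named by a rule fixed beforehand. It takes the 12 highest and 12 lowest log2 fold changes of the averaged comparison among genes that passed there and in both pairs with the same sign, the 10 highest and 10 lowest of each pair, the 5 highest and 5 lowest of each other comparison, up to 4 members per list and comparison with the largest change among those that passed (the 2 largest where none passed), and TERT, ISG15, CDH1, CDH2, VIM, KRT18, AMACR and MKI67. XIST and Y-linked genes were left out, and a few genes that the rule names are not reported here.

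RNA quality was read from the control probe sets of GAPDH and ACTB, as the signal at the 3' end minus that at the 5' end on the log2 scale, and compared between groups with 2-sided exact permutation tests. The pipeline was tested on simulated data with the groups of LhTERTL and mock and 20283 genes. It recovered 76.1% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, and 11 of 195 calls were unchanged genes. With no changed genes, simulated for LhTERTL/cre+ against mock/cre+, it called 0 genes, and camera called 1 of 1 shifted list and 0 of the unchanged lists. These simulated lists held 30 genes each and were not the real ones. The estimated correlation between genes of the real lists ran from -0.0018 for stem cell genes to 0.68 for interferon-stimulated genes. The simulation therefore cannot decide how often camera calls strongly correlated lists falsely. Alternatives covered the summary per gene, the normalization, filters by variance, array weights, robust variances, a replicate block, the lines as a random block, fits of only the groups compared, the GAPDH or ACTB 3' minus 5' difference as a covariate, single control lines, other list tests and leaving out each array. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.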

Results

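The series profiled 16 xenograft tumors, 4 from each of 4 PC-3 derivatives, to compare gene expression in tumors with long and with short telomeres, in the presence and in the absence of exogenous hTERT. The 8 tumors with long telomeres came from LhTERTL and LhTERTL/cre+, and the 8 with short telomeres from mock and mock/cre+. No 2 arrays were identical. Across genes, which are not independent replicates, the mean correlation between tumors of 1 line ran from 0.38 in LhTERTL/cre+ to 0.69 in mock/cre+, and that between tumors of different lines was -0.16. Single pairs of the latter ran from -0.52 to 0.56. The values are relative to the median of the same 16 arrays. Likeness within lines then pushes the mean between lines below 0, so it does not mean that whole profiles were opposed. The first principal component held 42.6% of the variance and the second 17.3%. The median log2 fold change of all genes lay between -0.02 and 0.02 in each of the 6 comparisons.

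RNA quality differed between the lines. The GAPDH 3' minus 5' difference was 0.50 ± 0.26 (SD, n = 4) in mock/cre+, against 0.13 ± 0.15 in mock, -0.02 ± 0.06 in LhTERTL and -0.07 ± 0.09 in LhTERTL/cre+. It was higher in mock/cre+ than in mock by 0.38 (exact permutation test, p = 0.0286, the smallest p that 4 against 4 allows), and lower in LhTERTL/cre+ than in mock/cre+, with a difference of -0.57 (exact permutation p = 0.0286). LhTERTL and mock differed by -0.15 (exact permutation p = 0.114). For ACTB the differences were 0.77, -0.85 and -0.15 (exact permutation p = 0.0286, 0.0286 and 0.4). All comparisons that include mock/cre+ therefore also compare RNA of different 3' to 5' balance.

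**Figure D1:**
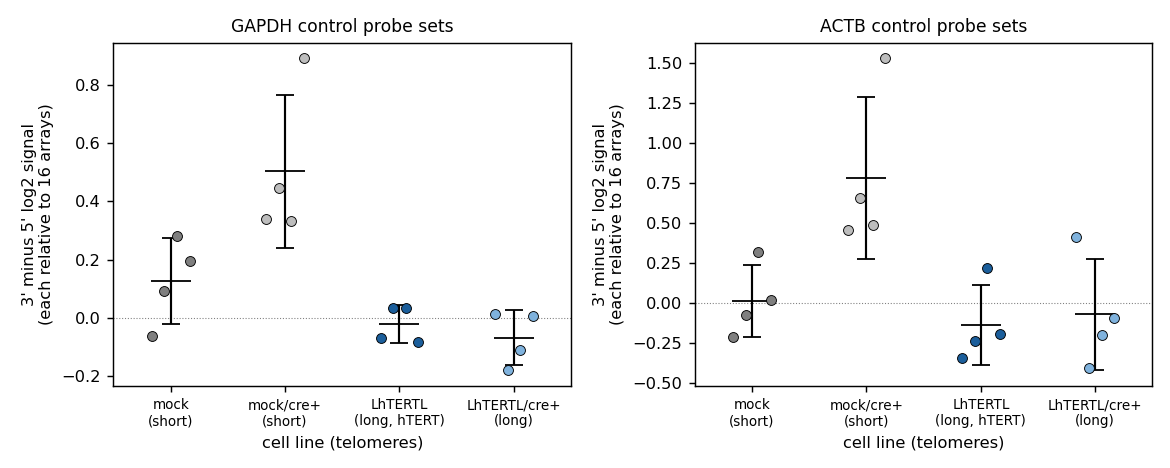
Log2 signal at the 3' end minus that at the 5' end of the GAPDH (left) and ACTB (right) control probe sets, each relative to its median over the 16 arrays, with 1 point per tumor and the mean ± SD of each line. The 4 mock/cre+ tumors lie between 0.33 and 0.89 for GAPDH, above the 12 other tumors.

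TERT, the gene introduced into the LhTERTL line, was read by 2 probe sets. On the first its signal was 3.10 ± 0.31 (SD, n = 4) in LhTERTL, against -0.03 ± 0.11 in mock, -0.17 ± 0.36 in mock/cre+ and 0.01 ± 0.21 in LhTERTL/cre+. LhTERTL exceeded mock by 3.13 ± 0.17 on the log2 scale, or 8.74-fold (limma adjusted p = 6.02e-09), and LhTERTL/cre+ lay below LhTERTL, with a log2 fold change of -3.08 ± 0.17 (adjusted p = 1.15e-08). LhTERTL/cre+ and mock/cre+ differed by 0.19 ± 0.17 (adjusted p = 0.477). The other probe set gave -0.58 ± 0.16 for LhTERTL against mock (adjusted p = 0.0181) and 0.47 ± 0.16 for LhTERTL/cre+ against mock/cre+ (adjusted p = 0.0409). Where its probes lie relative to the introduced sequence is not given in the sources used here, so it checks nothing about the labels.

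**Figure D2:**
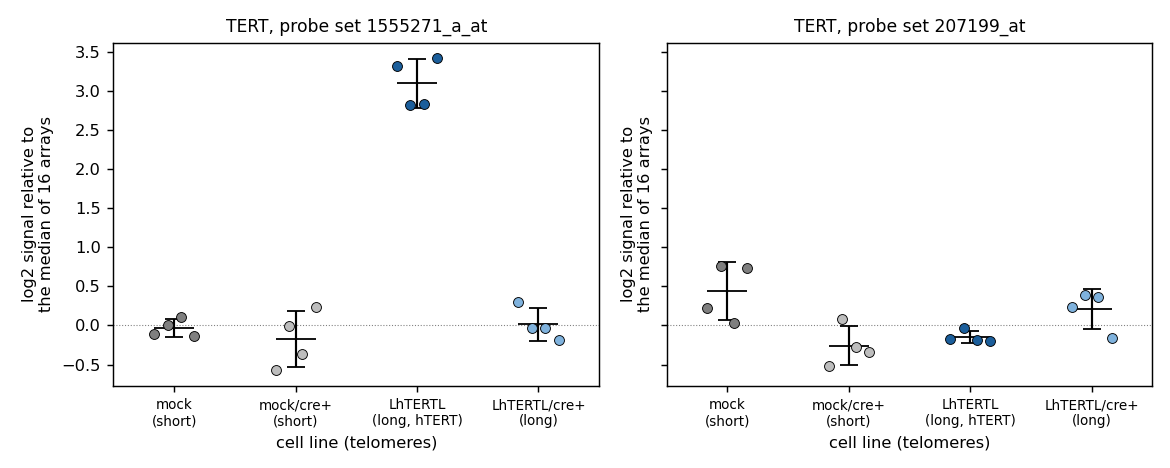
Log2 signal of the 2 TERT probe sets relative to the median of the 16 arrays, with 1 point per tumor and the mean ± SD of each line. On the first (left) the 4 LhTERTL tumors lie between 2.82 and 3.41, and the 12 other tumors between -0.57 and 0.30.

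Interferon-stimulated genes were lower and cell cycle genes higher in the tumors with long telomeres, averaged over both pairs of lines. All 44 interferon-stimulated genes measured fell, with a median log2 fold change of -1.86, and the list mean lay between -1.68 and -0.25 in the 8 long-telomere tumors against 0.29 to 1.69 in the 8 short-telomere tumors. Of 36 cell cycle genes, 33 rose, with a median of 0.65. The genes of antigen presentation also fell, 17 of 20, with a median of -0.51. The largest single change was EPB41L3, a membrane skeleton protein, at 4.10 ± 0.28 on the log2 scale or 17.2-fold higher (adjusted p = 1.26e-08).

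Among the interferon-stimulated genes, TRIM22, an antiviral ubiquitin ligase, changed by -2.97 ± 0.26, RSAD2 (viperin) by -2.79 ± 0.18, XAF1, which promotes apoptosis, by -2.69 ± 0.17, and BST2 (tetherin), which holds budding viruses on the cell surface, by -2.59 ± 0.19. The log2 fold changes of IFI44L, IFI44, HERC5, OAS1 and RTP4 were -2.48, -2.48, -2.47, -2.37 and -2.33. OAS1 makes the messenger that activates RNase L, and HERC5 attaches ISG15 to proteins. ISG15 itself, the ubiquitin-like modifier, changed by -1.55 ± 0.11 (adjusted p = 3.45e-08). TNFSF10 (TRAIL), a death ligand, at -3.14 ± 0.26, LAMP3 at -2.33 and CLTRN (collectrin), which assists amino acid transporters, at -2.51 were the other genes among the 12 with the largest decreases. The list's call had a camera adjusted p of 1.38e-51, and adjusted p = 0.115 with an estimated correlation. All 44 also passed when adjusted over the list alone.

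The antigen presentation genes that fell included PSMB9, a subunit of the immunoproteasome, at -1.15 ± 0.15, HLA-B at -1.03 ± 0.13 and B2M, the light chain of class I molecules, at -0.99 ± 0.09. This list had a camera adjusted p of 7.06e-13 and adjusted p = 0.115 with an estimated correlation, and 17 genes passed when adjusted over the list alone. In the NF-kB and inflammatory list 13 of 28 genes fell and 2 rose, with a median of -0.19 (camera adjusted p = 4.36e-04, adjusted p = 0.115 with an estimated correlation; 13 and 2 when adjusted over the list alone). CXCL11, a chemokine that interferon also induces, changed by -1.30 ± 0.18, BIRC3, an inhibitor of apoptosis, by -1.10 ± 0.13, and NFKBIA, the inhibitor of NF-kB, by -0.91 ± 0.09. MMP1, a collagenase of the same list, rose by 1.98 ± 0.18.

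Among the cell cycle genes, RRM2, a subunit of ribonucleotide reductase, rose by 1.06 ± 0.09, KIF20A, a mitotic kinesin, by 1.05 ± 0.10, CCNE2 (cyclin E2) by 1.04 ± 0.08, and CDK1, the mitotic kinase, by 0.99 ± 0.08. MKI67, the proliferation marker, rose by 0.80 ± 0.09 (adjusted p = 3.17e-06). The camera adjusted p was 2.08e-20, with adjusted p = 0.115 with an estimated correlation, and 35 genes rose when adjusted over the list alone. In the cholesterol and fatty acid synthesis list 15 of 26 genes rose and 0 fell, with a median of 0.22 (camera adjusted p = 2.61e-04, adjusted p = 0.484 with an estimated correlation; 16 when adjusted over the list alone). They included INSIG1, which restrains sterol synthesis, at 0.90 ± 0.14, STARD4, a cholesterol carrier, at 0.88 ± 0.16, FDFT1 (squalene synthase) at 0.81 ± 0.12 and CYP51A1 (lanosterol demethylase) at 0.54 ± 0.08.

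Mesenchymal genes rose in 14 of 24 cases and fell in 1, with a median of 0.29 (camera adjusted p = 1.39e-03, adjusted p = 0.115 with an estimated correlation; 15 and 1 when adjusted over the list alone). In LhTERTL against mock 5 rose and 1 fell, and the list did not pass (median 0.06, camera adjusted p = 0.462). S100A4, a calcium-binding protein, rose by 1.23 ± 0.21, GNG11, a G protein subunit, by 1.19 ± 0.17, and VIM (vimentin) by 0.44 ± 0.09 (adjusted p = 6.95e-04). Of the unfolded protein and amino acid stress genes 6 of 20 fell and 1 rose, with a median of -0.13 (camera adjusted p = 4.92e-03, adjusted p = 0.626 with an estimated correlation; 6 and 1 when adjusted over the list alone). Here too LhTERTL against mock did not pass, with 2 lower and 1 higher (median 0.01, camera adjusted p = 0.615). TRIB3 changed by -0.74 ± 0.07, DDIT3 (CHOP), a stress transcription factor, by -0.74 ± 0.10 and HSPA5 (BiP), the main chaperone of the endoplasmic reticulum, by -0.49 ± 0.10. CDH1 (E-cadherin) at 0.08 ± 0.17 and KRT18 (keratin 18) at 0.03 ± 0.08 did not pass (adjusted p = 0.779 and 0.823), nor did CDH2 (N-cadherin) at -0.09 ± 0.08 (adjusted p = 0.425), whose 2 probe sets went apart, with -0.31 and 0.13.

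The 12 genes with the largest increases in common to both pairs were led by EPB41L3 and HAS2, which makes hyaluronan, at 3.07 ± 0.24. SCN3A, a neuronal sodium channel, LOC100288985 and FABP4, a fatty acid carrier best known from adipocytes, followed at 2.80, 2.80 and 2.79. PRTFDC1, TFF3, a secreted trefoil peptide, GJB2 (connexin 26), TUBB6, a beta-tubulin, FBXL7, LYPD1 and PLPPR5 rose by 2.64, 2.59, 2.43, 2.42, 2.28, 2.13 and 2.10. Of the 7 host cell marker lists 0 passed the camera test, and the 15 macrophage and leukocyte markers had a median of 0.02 (camera adjusted p = 0.957). Whether the human probes detect the mouse transcripts of such cells is not known here.

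**Figure D3:**
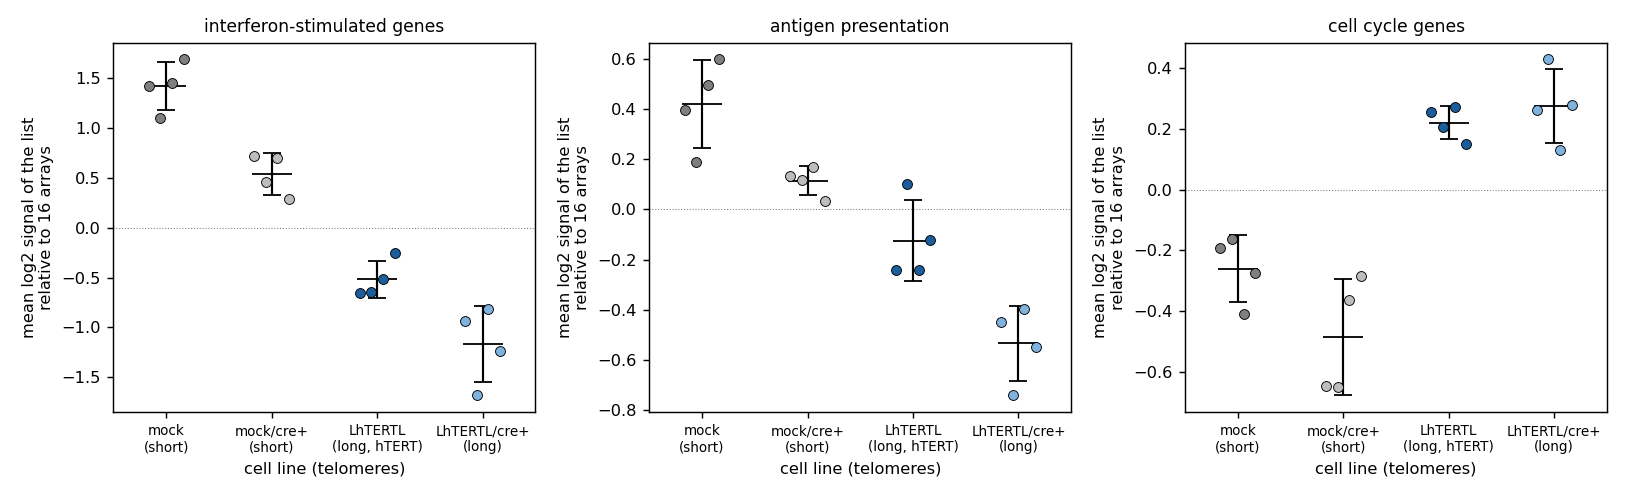
Mean log2 signal of the interferon-stimulated genes (left), the antigen presentation genes (middle) and the cell cycle genes (right), relative to the 16 arrays, with 1 point per tumor and the mean ± SD of each line. The interferon list means lie between 0.29 and 1.69 in the short-telomere tumors and between -1.68 and -0.25 in the long-telomere tumors, and the cell cycle means are below 0 in the first and above 0 in the second.

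In total 6604 of 20283 genes changed in this averaged comparison, 3744 higher and 2860 lower with long telomeres, so that 56.7% of the calls were higher, against 50.9% after a further quantile normalization. At least 2-fold changes were seen in 232 of them, 128 higher and 104 lower. The call of the mesenchymal list ended with the GAPDH difference as a covariate (6 of 24 rose and 0 fell, median 0.19, adjusted p = 0.112) and with mock as the only control (adjusted p = 0.334), where that of the unfolded protein list ended too (adjusted p = 0.185), and the NF-kB call ended with mock/cre+ as the only control (adjusted p = 0.284). With cell line as a random block 3025 genes passed, all of which had changed in the same direction, including 43 interferon-stimulated and 28 cell cycle genes. That fit used 1 correlation between tumors of a line, 0.20, for all genes. Genes that differ more than this between lines of 1 telomere state may pass too easily. Its p-values therefore do not treat the 2 lines per telomere state as the unit. The ACTB difference as a covariate gave 5804 genes. With the GAPDH difference as a covariate 3821 genes passed, without 10 of the 66 named genes called here, among them SCN3A (2.07, adjusted p = 0.066), STARD4 (0.71, 0.0645), HSPA5 (-0.42, 0.0804) and VIM (0.24, 0.235), while the median standard error of all genes went from 0.06 to 0.10. VIM also did not pass with the random block (0.44 as before, adjusted p = 0.0716), nor did VIM, S100A4 and GNG11 with mock as the only control, where their log2 fold changes were 0.14, 0.64 and 0.38 (adjusted p = 0.44, 0.0846 and 0.238). With mock as the only control 4345 genes passed, and with mock/cre+ as the only control 7000.

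The pairs of lines shared no tumor, so their log2 fold changes came from separate arrays. The calls were not separate, since the main fit pooled the spread of each gene over all lines. A gene with a small pooled spread passes more easily in both pairs. Separate tumors do not make the lines independent. By their names, the cre+ lines may derive from LhTERTL and mock. Both pairs would then share any other difference between those lines, so the overlap is not specific to telomere length. A total of 1225 genes rose in both pairs and 791 fell in both, against 374.5 and 210.4 that independent lists of these sizes would share. Opposite changes were found in 221 genes, against 567.2 for independent lists. Because of the pooled spread the lists are not independent, so these values are a reference only and no test of the overlap. The pooled spread alone does not favour the same direction over opposite directions. Across all 20283 genes, which are not independent replicates, the log2 fold changes of the pairs correlated with a Pearson r of 0.481 and a Spearman rho of 0.409. The effect differed in size between the pairs for 178 of the 2016 genes with shared direction. With the GAPDH covariate 1094 genes passed in both pairs in the same direction.

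**Figure D4:**
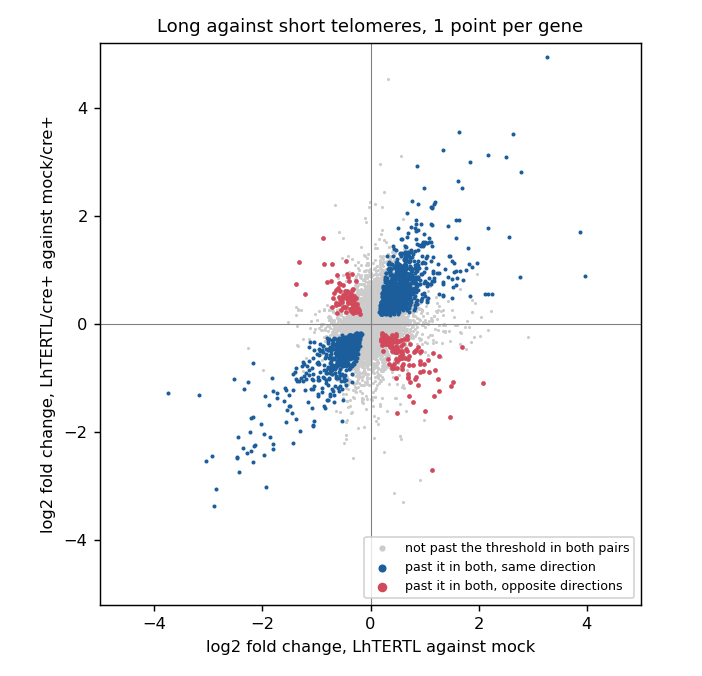
Log2 fold change of each of 20283 genes for LhTERTL against mock (horizontal) and for LhTERTL/cre+ against mock/cre+ (vertical). Blue points are the 2016 genes that passed in both pairs in the same direction, red points the 221 that passed in opposite directions, and grey points all others.

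With exogenous hTERT present, LhTERTL tumors had less expression of all 44 interferon-stimulated genes than mock tumors, with a median of -1.97, and more of 26 of 36 cell cycle genes, with a median of 0.52. The largest increases were GJB2, at 3.97 ± 0.28 on the log2 scale or 15.7-fold (adjusted p = 1.40e-07), and FABP4, at 3.88 ± 0.12 or 14.7-fold (adjusted p = 2.47e-12). The largest decreases were CLTRN, at -3.74 ± 0.29, and IFI27, an interferon-induced mitochondrial protein, at -3.17 ± 0.29. For both it was mock that stood apart from the other lines. The mean of CLTRN was 3.38 in mock, against -0.36 in LhTERTL, 0.42 in mock/cre+ and -0.86 in LhTERTL/cre+. That of IFI27 was 3.11 in mock, against -0.06, -0.03 and -1.34 in the same order. In the same comparison 11 of 28 hypoxia and glycolysis genes rose and 1 fell.

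The interferon list had a camera adjusted p of 6.55e-60, and adjusted p = 0.0889 with an estimated correlation, and all 44 genes fell when adjusted over the list alone. RSAD2, XAF1, TNFSF10, TRIM22, EPSTI1, HERC5, IFI44 and CMPK2 completed the 10 largest decreases, from -3.04 to -2.45. The cell cycle list (camera adjusted p = 5.65e-14, adjusted p = 0.266 with an estimated correlation, 28 genes when adjusted over the list alone) was led by RRM2 at 0.98 ± 0.13. In antigen presentation 17 of 20 genes fell, also when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 2.35e-11, adjusted p = 0.223 with an estimated correlation). Of the NF-kB genes 11 fell and 2 rose, also when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 1.29e-03, adjusted p = 0.223 with an estimated correlation). They included the neutrophil chemokines CXCL2 at -1.37 ± 0.15 and CXCL8 (interleukin 8) at -1.29 ± 0.17. In the cholesterol list 8 of 26 genes rose, and 13 when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 2.21e-03, adjusted p = 0.575 with an estimated correlation).

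The hypoxia list, with a median of 0.19, had a camera adjusted p of 2.25e-03, and adjusted p = 0.266 with an estimated correlation, and 11 rose and 2 fell when adjusted over the list alone. ALDOC (aldolase C) rose by 0.59 ± 0.10, NDRG1 by 0.57 ± 0.09 and BNIP3, a mitophagy receptor, by 0.56 ± 0.08. RAI2, ASS1 (argininosuccinate synthase), HAPLN1, which links hyaluronan to proteoglycans, and HTR2B, a serotonin receptor, were among the 10 largest increases at 2.92, 2.77, 2.56 and 2.25, beside EPB41L3, SCN3A, HAS2 and LOC100288985. AMACR (racemase), a prostate cancer marker, rose by 0.43 ± 0.09 (adjusted p = 2.84e-03). In total 4114 genes changed, 2494 higher and 1620 lower (60.6% higher, against 53% after a further quantile normalization), and 278 by at least 2-fold. Of the 55 named genes called here, 0 lost the call with the GAPDH covariate.

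Without exogenous hTERT, LhTERTL/cre+ tumors had less expression of 43 of 44 interferon-stimulated genes than mock/cre+ tumors, with a median of -1.68, and more of 32 of 36 cell cycle genes, with a median of 0.73. Epithelial junction and keratin genes fell in 14 of 34 cases and rose in 3, while 13 of 24 mesenchymal genes rose and 1 fell. EPB41L3 rose by 4.93 ± 0.39 or 30.6-fold (adjusted p = 1.98e-07) and HSD17B2, which inactivates estradiol and testosterone, by 4.52 ± 0.45 or 23-fold (adjusted p = 1.51e-06). TNFSF10 changed by -3.37 ± 0.36, and the fibrinogen chains FGG and FGB by -3.31 ± 0.57 and -3.14 ± 0.75. For HSD17B2, FGG and FGB it was mock/cre+ that stood apart from the other lines. The mean of HSD17B2 was -3.36 in mock/cre+, against 0.03 in mock, 0.36 in LhTERTL and 1.16 in LhTERTL/cre+. Those of FGG and FGB were 2.34 and 2.66 in mock/cre+, against -0.09 and -0.22 in mock.

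The interferon list had a camera adjusted p of 3.27e-40 and adjusted p = 0.151 with an estimated correlation, and the cell cycle list 1.37e-20 and adjusted p = 0.169 with an estimated correlation. Adjusted over the list alone, 43 interferon genes fell and 33 cell cycle genes rose. KIF20A, CCNE2 and CDK1 rose by 1.36, 1.33 and 1.30. In antigen presentation 15 of 20 genes fell, and 16 when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 2.59e-10, adjusted p = 0.169 with an estimated correlation). The unfolded protein list fell in 11 of 20 cases, also when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 1.23e-04, adjusted p = 0.426 with an estimated correlation). ATF4, the amino acid stress transcription factor, changed by -0.58 ± 0.08. In the cholesterol list 9 of 26 genes rose, also when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 1.20e-03, adjusted p = 0.513 with an estimated correlation). In the NF-kB list 9 of 28 fell and 1 rose, also when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.0169, adjusted p = 0.415 with an estimated correlation), led by CXCL11 at -2.13 ± 0.26. Without LhTERTL/cre+ tumor 1 the NF-kB list had an adjusted p of 0.0503.

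ESRP1, a splicing regulator of epithelial cells, changed by -2.90 ± 0.45, DSP (desmoplakin) by -1.93 ± 0.33, EPCAM, an epithelial adhesion molecule, by -1.34 ± 0.34 and MARVELD2 (tricellulin) by -1.25 ± 0.16. The epithelial list had a median of -0.20, a camera adjusted p of 7.57e-04 and adjusted p = 0.426 with an estimated correlation, with 14 lower and 3 higher when adjusted over the list alone. On the mesenchymal side GNG11 rose by 2.17 ± 0.24, SNAI2 (Slug), which represses CDH1, by 1.12 ± 0.15, CDH11, a mesenchymal cadherin, by 0.98 ± 0.11 and VIM by 0.87 ± 0.12 (adjusted p = 4.94e-05). That list had a median of 0.35, a camera adjusted p of 2.66e-04 and adjusted p = 0.151 with an estimated correlation, with 14 higher and 1 lower when adjusted over the list alone. TFF3, HAS2, FBXL7, PRTFDC1, ANXA10, LOC100288985, TUBB6 and TFF2, a gastric trefoil peptide, completed the 10 largest increases, from 3.55 to 2.95. The means of TFF2 and ANXA10 were -2.53 and -2.52 in mock/cre+, against 0.06 and -0.43 in mock. The remaining largest decreases were TRIM22, IFI44L, BST2, EYA1, a developmental transcription cofactor, OAS1 and RSAD2, from -3.07 to -2.54.

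In total 5680 genes changed in this pair, 3046 higher and 2634 lower (53.6% higher, against 49.8% with each array centred on its median), and 489 by at least 2-fold. With the ACTB difference as a covariate 4231 genes passed in this pair, so the count depended on the control chosen. With the GAPDH difference as a covariate 1866 genes passed, and 24 of the 60 named genes called here no longer did. They include FGB (-3.40 with the covariate, adjusted p = 0.133), SNAI2 (0.88, 0.0527), ESRP1 (-2.43, 0.0696), EPCAM (-0.92, 0.374), DSP (-1.34, 0.159), CDH1 (-0.59, 0.436), KRT18 (-0.41, 0.235) and VIM (0.54, 0.0973), while the median standard error of all genes went from 0.09 to 0.15. With the covariate 36 interferon and 6 antigen presentation genes fell, 26 cell cycle, 6 mesenchymal and 2 cholesterol genes rose, 4 unfolded protein and 3 NF-kB genes fell and 1 rose, and of the epithelial genes 1 rose and 1 fell, with a median of -0.15.

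EPCAM, CDH1 and KRT18 changed in opposite directions in the pairs of lines. The epithelial list as a whole passed without exogenous hTERT (adjusted p = 0.426 with an estimated correlation) and not with it (6 of 34 rose and 3 fell, median 0.11, camera adjusted p = 0.462). CDH1 was 0.91 ± 0.24 higher in LhTERTL than in mock (adjusted p = 0.0111) and changed by -0.75 ± 0.24 in LhTERTL/cre+ against mock/cre+ (adjusted p = 0.0247), a difference of 1.65 ± 0.34 (adjusted p = 4.42e-03). Its change came from 1 of its 2 probe sets, and the other gave 0.04 and 0.05. The decrease did not pass without mock/cre+ tumor 1 or 3 or LhTERTL/cre+ tumor 1 or 2 (adjusted p = 0.0597, 0.0796, 0.0607 and 0.0932), and it was -0.47 without the last of these. KRT18 changed by 0.58 ± 0.12 and -0.51 ± 0.12, a difference of 1.09 ± 0.16 (adjusted p = 5.74e-04), and EPCAM by 1.18 ± 0.34 and -1.34 ± 0.34, a difference of 2.52 ± 0.47 (adjusted p = 2.74e-03). The increase of EPCAM in LhTERTL did not pass without mock tumor 1, 2 or 4 or LhTERTL tumor 3 (adjusted p = 0.0525, 0.0548, 0.0624 and 0.0531). CDH2 changed by -0.47 ± 0.11 with exogenous hTERT (adjusted p = 6.48e-03) and gave 0.28 ± 0.11 without it (adjusted p = 0.0734). On its probe set with the largest variance the change with exogenous hTERT was -0.27 and did not pass (adjusted p = 0.235). VIM gave 0.02 ± 0.12 with exogenous hTERT (adjusted p = 0.954) and rose by 0.87 ± 0.12 without it. The effects of CDH2 and VIM differed between the pairs by -0.75 ± 0.16 and -0.85 ± 0.17 (adjusted p = 5.79e-03 and 4.45e-03).

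The comparison asked whether the effect of telomere elongation depended on exogenous hTERT. A total of 2151 genes passed, 1141 with a more positive effect in the pair with exogenous hTERT and 1010 with a more negative one. The same value is the difference between the control lines minus that between the long-telomere lines, where 3863 and 657 genes changed. Between the control lines KRT18, CDH2 and VIM changed by 0.91, -0.79 and -0.61. Between the long-telomere lines they gave -0.18, -0.04 and 0.24, without passing. For CDH1 the values were 0.91 and -0.74. A dependence on hTERT therefore cannot be told apart from a difference between the control lines. Of the epithelial genes 9 of 34 were more positive and 1 more negative, and 16 and 3 when adjusted over the list alone, with a median difference of 0.33 (camera adjusted p = 1.29e-04, adjusted p = 0.840 with an estimated correlation). The mesenchymal list had a median difference of -0.29, with 3 more positive and 8 more negative (3 and 10 when adjusted over the list alone, camera adjusted p = 8.44e-03, adjusted p = 0.671 with an estimated correlation). For the cell cycle list the median was -0.30, with 7 of 36 genes more negative (13 when adjusted over the list alone, camera adjusted p = 4.91e-05, adjusted p = 0.840 with an estimated correlation), and for the unfolded protein list 0.30, with 4 of 20 genes more positive (7 when adjusted over the list alone, camera adjusted p = 1.30e-03, adjusted p = 0.840 with an estimated correlation). The interferon list did not pass (median -0.04, camera adjusted p = 0.0995), and 6 of its 44 genes had a more negative effect with exogenous hTERT. The largest single differences were FGG, EYA1, ESRP1, FGB and KRT75, a keratin of the hair follicle, at 3.90, 3.84, 3.81, 3.57 and 3.19, and HSD17B2, BCL2A1, an anti-apoptotic BCL2 relative, TFF2, ANXA10 and PLAT (tissue plasminogen activator) at -4.19, -2.87, -2.78, -2.54 and -2.48. With the GAPDH covariate 2 epithelial genes were more positive and 0 more negative, 2 and 3 of the mesenchymal, 0 and 1 of the cell cycle and 0 and 0 of the unfolded protein genes. In that fit 535 genes passed in total, while the ACTB difference as a covariate gave 1224 genes and array weights 3339. CDH1, CDH2, VIM, FGB and TERT did not pass with the GAPDH covariate (adjusted p = 0.0705, 0.0601, 0.118, 0.167 and 0.0588). Their differences were 1.54, -0.76, -0.61, 3.76 and 0.83 in place of 1.65, -0.75, -0.85, 3.57 and 0.95. The call of FGB ended in 11 of the 16 fits that left out 1 tumor (adjusted p from 0.0514 to 0.0893).

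**Figure D5:**
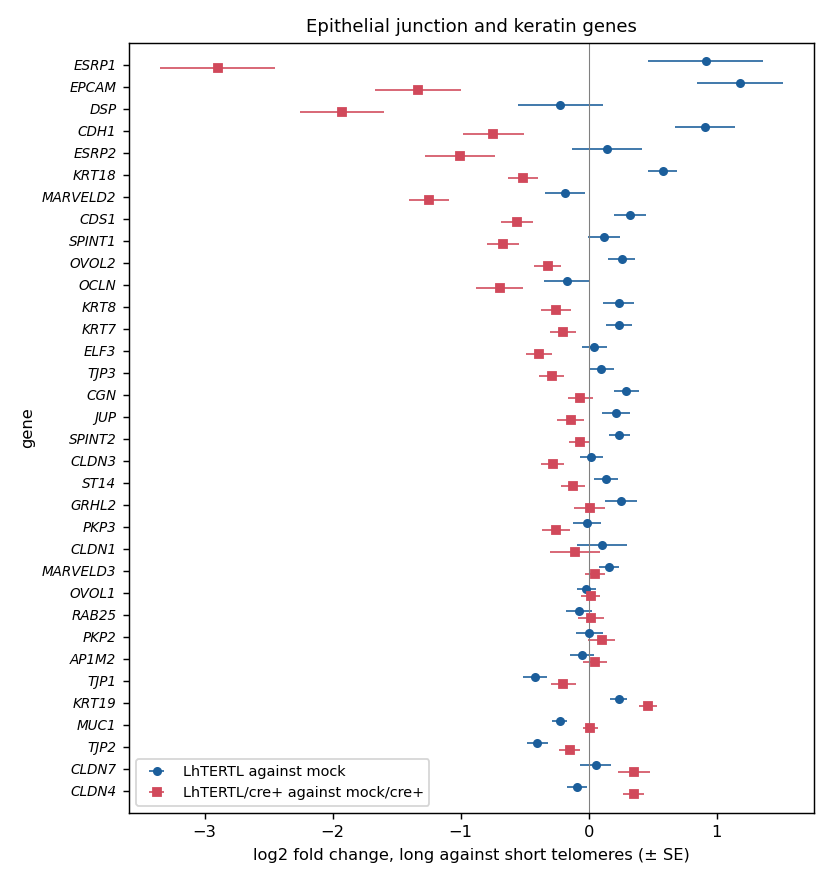
Log2 fold change ± SE of the 34 epithelial junction and keratin genes, long against short telomeres, for LhTERTL against mock (circles) and LhTERTL/cre+ against mock/cre+ (squares), ordered by the difference between the pairs. EPCAM, CDH1 and KRT18 passed with opposite signs in the pairs.

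The control lines mock and mock/cre+ had the same telomere state and no exogenous hTERT, and still differed widely. Interferon-stimulated genes were lower in mock/cre+, 28 of 44, with a median of -0.76, led by MX1 at -3.45 ± 0.27, IFI27 at -3.14 ± 0.29, MX2 at -2.41 ± 0.19 and EPSTI1 at -2.03 ± 0.22. MX1 and MX2 encode antiviral GTPases. Epithelial genes were higher in 10 of 34 cases and lower in 2, with ESRP1 at 2.53 ± 0.45, EPCAM at 1.66 ± 0.34, DSP at 1.09 ± 0.33 and KRT18 at 0.91 ± 0.12, while CDH2 changed by -0.79 ± 0.11 and CLDN1 (claudin 1) by -1.22 ± 0.20. FGB, FGG, KRT75 and PRKAR2B, a regulatory subunit of protein kinase A, were higher by 2.88, 2.43, 2.22 and 2.20, and HSD17B2, CLTRN and NME5 changed by -3.39, -2.96 and -2.82.

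In total 3863 genes changed between the control lines, 1825 higher and 2038 lower in mock/cre+, so that 47.2% were higher, against 51.2% after a further quantile normalization. Lists that passed were the interferon genes (camera adjusted p = 1.89e-16, adjusted p = 0.573 with an estimated correlation, 31 lower when adjusted over the list alone), the cell cycle genes (11 of 36 lower, median -0.22, camera adjusted p = 9.66e-04, adjusted p = 0.753 with an estimated correlation, 12 lower and 1 higher when adjusted over the list alone) and antigen presentation (6 of 20 lower, also when adjusted over the list alone, median -0.22, camera adjusted p = 1.68e-03, adjusted p = 0.622 with an estimated correlation). The mesenchymal genes (11 lower and 3 higher, median -0.27, camera adjusted p = 5.15e-03), the NF-kB genes (10 lower and 3 higher, median -0.19, camera adjusted p = 5.15e-03), the hypoxia genes (11 lower and 2 higher, median -0.20, camera adjusted p = 0.0164) and the epithelial genes (median 0.17, camera adjusted p = 0.0109) passed as well, with adjusted p = 0.569, 0.569, 0.573 and 0.622 with an estimated correlation. Adjusted over the list alone, these lists had 11 lower and 4 higher, 12 and 3, 14 and 5, and 4 and 12. With the GAPDH covariate 14 interferon, 4 cell cycle and 3 antigen presentation genes were lower, 3 epithelial genes higher and 2 lower, 7 mesenchymal genes lower and 1 higher, 7 NF-kB genes lower and 1 higher, and 2 hypoxia genes lower and 1 higher. In that fit 1513 genes passed in total, but not FGB and FGG (adjusted p = 0.1 and 0.0653), whose log2 fold changes were 3.05 and 2.59 with the covariate against 2.88 and 2.43 without it. FGB did not pass without mock tumor 4 (adjusted p = 0.0508). The ACTB difference as a covariate gave 2086 genes.

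Between the long-telomere lines, the interferon-stimulated genes were lower in LhTERTL/cre+, which lacks exogenous hTERT, than in LhTERTL, 15 of 44, with a median of -0.60. Hypoxia and glycolysis genes were lower in 9 of 28 cases, with a median of -0.22, among them DDIT4, an inhibitor of mTOR signalling, at -1.04 ± 0.16 and BNIP3 at -0.72 ± 0.08. The cell cycle list did not pass (median 0.06, camera adjusted p = 0.0538, 0 genes past the threshold). GJB2 and RAI2 changed by -3.64 ± 0.28 and -3.16 ± 0.23, CP (ceruloplasmin) by -2.91 ± 0.27, FAM9A by -2.62 ± 0.23 and TENM2 by -2.60 ± 0.37. TMEM200A at 2.71, TCN1, a vitamin B12 carrier, at 1.83, ANKRD36C at 1.30, PDE2A, a phosphodiesterase, at 1.29 and CADPS2 at 1.09 were the largest increases.

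In total 657 genes changed, 187 higher and 470 lower in LhTERTL/cre+, so that 28.5% of the calls were higher, against 42.1% after a further quantile normalization. The lists that passed were the interferon genes (camera adjusted p = 4.72e-22, adjusted p = 0.250 with an estimated correlation, 33 lower when adjusted over the list alone), hypoxia (camera adjusted p = 6.02e-13, 16 lower when adjusted over the list alone), which was the only one that passed with an estimated correlation (adjusted p = 0.0110), antigen presentation (9 of 20 lower, median -0.41, camera adjusted p = 2.42e-08) and the NF-kB genes (3 of 28 lower, median -0.16, camera adjusted p = 1.77e-05), with adjusted p = 0.250 and 0.0985 with an estimated correlation. Adjusted over the list alone, antigen presentation had 12 lower and 1 higher and the NF-kB genes 10 lower. Epithelial genes (3 lower and 2 higher, median -0.17, camera adjusted p = 1.37e-03), unfolded protein genes (1 lower, median -0.12, camera adjusted p = 0.0182), TGF-beta targets (TGFBI at -1.92 ± 0.28 and ID3 at -1.40 ± 0.21 fell, median -0.07, camera adjusted p = 0.0266) and basal epithelial genes (2 lower, median -0.10, camera adjusted p = 0.0429) had adjusted p = 0.460, 0.583, 0.240 and 0.383 with an estimated correlation. The count rested on single tumors, since it was 265 without LhTERTL/cre+ tumor 2, 393 without tumor 3 and 992 without tumor 4 of that line, and 374 and 312 without LhTERTL tumors 1 and 2. TCN1 did not pass without LhTERTL tumor 2 or LhTERTL/cre+ tumor 1 or 3 (adjusted p = 0.0812, 0.0524 and 0.0681), nor CADPS2 without LhTERTL tumor 1 or 4 or LhTERTL/cre+ tumor 1, 2 or 3 (adjusted p from 0.0515 to 0.0644). The count was 257 in a fit of these 8 tumors alone and 1261 with array weights.

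No excess of changed genes was detected at chromosome ends, the nearest to telomeres, in the averaged comparison. Of the 1170 autosomal genes among the 30 outermost per chromosome end, 32.65% had changed, against 33.43% of the other 17311 (permutation test of a higher share, p = 0.711). Their median log2 fold change was 0.01, against 0.02 for the others. Among the 10 outermost per end the share was higher, 35.13% against 33.34%, without passing (permutation p = 0.239). For the 100 outermost it was 33.36% against 33.39% (permutation p = 0.522).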

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

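Of the tests in this part, those of host leukocytes, of the share of PC-3 cells and of the line difference for the interferon genes were chosen only after the result was seen. The interferon-stimulated genes fell in the long-telomere tumors, with a median of -1.86 on the log2 scale. Differing RNA quality would weaken the change once modelled, and with the GAPDH difference as a covariate the median was -1.96. Fewer host leukocytes cannot be told apart, since 2 of their 15 markers changed in any comparison, and a median of 0.0165 decides nothing where human probes may not detect mouse transcripts. A trait of the lines other than telomere length cannot be told apart from telomere elongation, since the 4 lines allow 3 splits into pairs, of which 1, the real one, gave a difference as large, and no smaller share was possible. The list means also differed by -0.88 between the short-telomere lines and by -0.65 between the long-telomere lines, against -1.82 between the telomere states, so a lower interferon response with long telomeres stays a hypothesis.

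The cell cycle genes rose in the long-telomere tumors, with a median of 0.65. With the GAPDH difference as a covariate the median was 0.73, which argues against RNA quality as the whole cause. A larger share of PC-3 cells would raise the epithelial genes too, whose median was -0.0202. The median of that list was 0.11 with and -0.20 without exogenous hTERT. Its genes thus changed for other reasons between the lines, so the averaged value cannot measure the share and decides nothing. Here too 1 of the 3 splits of the lines, the real one, gave a difference as large, the smallest share possible, so telomere elongation and another trait of the lines cannot be told apart. The list means differed by 0.62 between the telomere states, against -0.09 and -0.14 for the other splits, by -0.23 between the short-telomere lines and by 0.05 between the long-telomere lines.

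The lines mock and mock/cre+ had the same telomere state and differed in 3863 genes. Copy number differences of wide chromosome regions would vanish once each gene is set against the median of its 50 neighbours on either side. In that test 3308 genes passed. Of these, 2975 were among the 3609 that had passed of the genes with a position, with the same sign. This argues against wide regions as the whole cause. Regions smaller than most of such a window are not removed, so the test cannot decide about them. Neighbouring genes did move together (correlation 0.18, against at most 0.02 in 1000 shuffles, with windows from -0.22 on chromosome 14 to 0.19 on chromosome 9), so regional differences may account for a part. Differing RNA quality cannot be told apart from the line, since mock/cre+ had the highest 3' to 5' difference. With the GAPDH difference as a covariate 1513 genes passed, the median absolute log2 fold change of the 3863 genes went from 0.40 to 0.38 and its standard error from 0.09 to 0.12, and all kept their sign, while an effect of cre stays open and was not tested.

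The real grouping by line gave more changed genes than any other split of the tumors in 6 results. The splits move single tumors, and those that mix the lines place the differences between lines within the groups. A chance difference between the few lines therefore cannot be excluded by them. With 35 splits of 8 tumors, the real counts and the highest of the other splits were 4114 and 1 for LhTERTL against mock, 5680 and 237 for LhTERTL/cre+ against mock/cre+, 3863 and 32 for the short-telomere lines and 657 and 86 for the long-telomere lines. With 100 splits of 16 tumors, they were 6604 and 1018 for the averaged comparison and 2016 and 0 for the genes shared by both pairs. For the difference between the pairs, 2 of 100 splits gave a count as large, with 2151 for the real one and 3859 for the other. That other split had 7 of the 8 long-telomere tumors on 1 side, so it points to a structure of the samples.

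Single tumors lay far from the 3 others of their line in 35 of 468 groups of 4 values tested, in 108 genes and 9 list means, where chance gives about 1 in 20. The value in brackets is the gap to the nearest tumor divided by the range of the 4, with a limit of 0.829. In LhTERTL/cre+, tumor 4 stood apart for HAS2 (0.922), PLPPR5 (0.901), HSD17B2 (0.904), FDFT1 (0.89), S100A4 (0.852) and ZMAT3 (0.918). In LhTERTL, tumor 1 stood apart for GJB2 (0.839) and LIN28B (0.852). In LhTERTL, tumor 4 stood apart for XAF1 (0.847), IFI44 (0.868), OAS1 (0.906), PDE2A (0.844) and CXCL11 (0.933). In LhTERTL/cre+, tumor 2 stood apart for HERC5 (0.905), OAS1 (0.896), FGG (0.881), KRT18 (0.917) and KIF20A (0.873). In mock, tumor 3 stood apart for HAPLN1 (0.853), KRT18 (0.93), MMP9 (0.845), DSP (0.839), EPCAM (0.866), CDH11 (0.876) and the mean of the epithelial junction and keratin genes (0.94). In mock, tumor 4 stood apart for PDE2A (0.958), CDH2 (0.889), STARD4 (0.953), CYP51A1 (0.869) and the mean of the cholesterol and fatty acid synthesis genes (0.847). In LhTERTL/cre+, tumor 3 stood apart for TENM2 (0.912). In mock/cre+, tumor 4 stood apart for HLA-C (0.887). In mock/cre+, tumor 2 stood apart for BIRC3 (0.898). In LhTERTL, tumor 2 stood apart for ZMAT3 (0.833) and DPP4 (0.834).

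The difference between the long-telomere and the short-telomere line was not the same in both pairs, by limma's test of the difference itself, for the genes below, while 2151 genes passed that test in all and 535 with the GAPDH difference as a covariate. The pairs also differ in the lines used and in RNA quality. In log2 units, LhTERTL against mock minus LhTERTL/cre+ against mock/cre+, it was 3.90 for FGG, 3.84 for EYA1, 3.81 for ESRP1, 3.57 for FGB, 3.19 for KRT75, 3.17 for RAI2, 3.17 for CP, 3.09 for GJB2, 2.62 for ID3, 2.52 for EPCAM, 2.25 for TGFBI, 2.24 for PRKAR2B, 2.19 for MMP9, 2.18 for FABP4, 1.91 for ASS1, 1.87 for FAM9A, 1.70 for DSP, 1.69 for HTR2B, 1.68 for CXCL11, 1.65 for CDH1, 1.09 for KRT18, 1.06 for MARVELD2, 1.02 for SPOCK1, 0.98 for DDIT4, 0.95 for TERT, 0.84 for FDFT1, 0.51 for ATF4 and 0.48 for NDRG1. In the other direction it was -4.19 for HSD17B2, -2.87 for BCL2A1, -2.78 for TFF2, -2.54 for ANXA10, -2.48 for PLAT, -2.46 for CLTRN, -2.46 for PDE2A, -2.18 for NME5, -1.95 for GNG11, -1.91 for TFF3, -1.89 for FBXL7, -1.86 for IFI27, -1.81 for MX1, -1.70 for SYT1, -1.56 for CXCL8, -1.50 for EPSTI1, -1.45 for MX2, -1.33 for CXCL2, -1.17 for SNAI2, -1.15 for TUBB6, -1.09 for CDH11, -0.85 for VIM, -0.77 for TP53I3, -0.75 for CDH2, -0.61 for CDK1 and -0.58 for CCNE2. The lists that differed had medians of -0.30 for the cell cycle genes, 0.33 for the epithelial junction and keratin genes, -0.29 for the mesenchymal genes and 0.30 for the unfolded protein and amino acid stress genes, with adjusted p = 0.84, 0.84, 0.671 and 0.84 with an estimated correlation. The value of TERT averages probe sets that went apart, with 2.94 and -1.05, and the first of these was high in LhTERTL, which carries exogenous hTERT. That of CDH1 came from 1 of its 2 probe sets.

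Among the 12172 probe sets without a gene name, which no comparison of genes used, 2503 had changed in the averaged comparison.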

How the results depend on the processing

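Of the alternatives, the probe set with the largest variance, the filters by variance, robust variances, the GAPDH and ACTB covariates and the single control lines were added after the data were seen. The GAPDH covariate was added once the RNA quality was known but before any fit with it. Leaving out 1 array gave 5392 values for called genes, of which 5226 kept their direction and call, 166 lost the call and 0 reversed. Counts of changed genes ran from 6068 to 6889 for the averaged comparison, 3140 to 4364 for LhTERTL against mock, 4599 to 6019 for LhTERTL/cre+ against mock/cre+, 1544 to 2721 for the difference between pairs, 2867 to 4182 for the short-telomere lines, 265 to 992 for the long-telomere lines and 1644 to 2208 for the shared genes. The lists called ran from 7 to 9, 6 to 6 and 7 to 8. The GAPDH covariate gave 3821, 1866, 535, 1513 and 1094 genes for the averaged comparison, LhTERTL/cre+ against mock/cre+, the difference between pairs, the short-telomere lines and the shared genes. The ACTB covariate gave 5804, 4231, 1224 and 2086 genes for the same comparisons, without a count of shared genes. With the GAPDH covariate the median standard error rose from 0.06 to 0.10 in the averaged comparison and from 0.09 to 0.15 without exogenous hTERT, with slopes of 1.00 and 0.94 between the log2 fold changes. Array weights gave 3339 genes for the difference between pairs and 1261 for the long-telomere lines, and a fit of the latter's 8 arrays alone 257. Cell line as a random block gave 3025 genes in the averaged comparison and mock as the only control 4345, against 7000 with mock/cre+ as the only control. The cause of these moves was not tested. Camera with an estimated correlation called 0, 0 and 0 lists and fry 16, 12 and 15. Against mock alone ESRP1 reversed from -0.99 to 0.27 and DPP4 from 0.50 to -0.0556, and against mock/cre+ alone SYT1 reversed from -0.54 to 0.26, without passing the test (adjusted p = 0.716, 0.856 and 0.172), and the cause was not tested. A block for the replicate number gave 6670, 4128, 5711, 2178, 3857 and 616 genes and 2010 shared ones. The pairing by number had little basis. With the group means taken off, 0 of 16 arrays correlated best, among arrays of other lines, with an array of their own number. The mean correlation was 0.04 for the same number, against -0.01 for other numbers. Mean-based filters, trend models, the highest mean probe set and the series matrix values were not run, because the centred values hold no level and the matrix was identical. Signal over background is lost for the same reason.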

Other observations

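Prostate luminal genes did not pass camera's test as a list (6 of 22 rose and 1 fell, median 0.09, camera adjusted p = 0.0991) in the averaged comparison. HOXB13, a homeobox factor of the prostate, rose by 1.21 ± 0.12. Among 25 p53 targets 6 rose and 2 fell (median 0.00, camera adjusted p = 0.574), including TP53I3 at 0.93 ± 0.10 and ZMAT3 at 0.63 ± 0.08. Of 16 stem cell genes 5 rose and 4 fell (median 0.05, camera adjusted p = 0.750), with LIN28B, an RNA-binding protein that blocks let-7, at 0.80 ± 0.13. Of 27 telomere maintenance genes 9 rose and 2 fell (median 0.09, camera adjusted p = 0.422), including TEN1, of the CST complex, at 0.49 ± 0.09. Hypoxia genes rose in 15 of 28 cases and fell in 6 (median 0.18, camera adjusted p = 0.0571), and epithelial genes rose in 1 of 34 and fell in 7 (median -0.02, camera adjusted p = 0.16). With fry the prostate luminal, p53, stem cell, telomere maintenance and hypoxia lists did pass (fry adjusted p = 4.13e-04, 4.13e-04, 0.0104, 3.66e-03 and 2.48e-04). The epithelial list did not (fry adjusted p = 0.302).

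Wnt targets (3 of 16 rose and 1 fell, median 0.04, camera adjusted p = 0.422), TGF-beta targets (4 of 18 rose and 5 fell, median 0.00, camera adjusted p = 0.574), basal epithelial genes (6 of 20 rose and 2 fell, median 0.08, camera adjusted p = 0.538), neuroendocrine genes (0 of 15 rose and 2 fell, median 0.03 and mean -0.07, camera adjusted p = 0.656) and cancer-testis antigens (1 of 16 rose, median 0.01, camera adjusted p = 0.964) did not pass either. Nor did the markers of fibroblasts (4 of 16 rose, median 0.07, camera adjusted p = 0.369), endothelium (3 of 13 rose and 1 fell, median 0.05, camera adjusted p = 0.656), macrophages and leukocytes (1 of 15 rose and 1 fell, median 0.02, camera adjusted p = 0.957), red blood cells (0 of 7, median 0.01, camera adjusted p = 0.964), skeletal muscle (1 of 15 rose, median 0.04, camera adjusted p = 0.964), adipocytes (3 of 10 rose, median 0.02, camera adjusted p = 0.468) and skin keratinocytes (1 of 11 rose and 1 fell, median -0.02, camera adjusted p = 0.911). With fry the Wnt, basal epithelial, fibroblast and adipocyte lists did pass (fry adjusted p = 0.0143, 0.035, 9.69e-03 and 3.9e-05), and the other lists of this paragraph did not. KDR, a receptor of vascular growth factors, changed by -1.18 ± 0.16. For the TGF-beta, neuroendocrine, leukocyte, red blood cell and muscle lists camera's direction was down while the median was above 0, and for the keratinocyte list the mean lay above 0 and the median below.

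The hypothesis that genes near chromosome ends respond more to telomere elongation was tested by permutation over the 30 outermost genes per end, with p = 0.711. Log2 fold changes of neighbouring genes were correlated, with 0.18 for LhTERTL against mock, 0.17 for LhTERTL/cre+ against mock/cre+, 0.18 for the short-telomere lines and 0.14 for the long-telomere lines, against at most 0.02 in 1000 shuffles (permutation p = 0.000999, the smallest possible). The largest shifts of a window of 101 genes were 0.32 on chromosome 6 without exogenous hTERT and -0.26 on chromosome 14 with it.

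Of the probe sets without a gene name, the lowest log2 fold changes of the averaged comparison were -2.66 ± 0.16 (adjusted p = 1.59e-08) and -2.11 ± 0.23, and the highest 2.06 ± 0.22 and 1.69 ± 0.14.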
